A study of Homo sapiens with 52 samples.

How the data were processed

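Gene expression was measured on 1-colour (Cy3) whole-genome oligonucleotide arrays in BEAS-2B cells, an established line derived from human bronchial epithelium. Per the labels, the cells were exposed for 48 h to 1 of 8 cellulose nanofibril preparations (CNF1 to CNF8, each at 100 µg/mL), to microcrystalline cellulose (MCC), or to vehicle. The concentration of MCC is not given in the sources used here, and the preparations are known here by their codes only. The 52 samples form 13 groups of 4. The labels name 4 vehicle control groups, each tied to its exposures: 1 for CNF1 and CNF3, 1 for CNF2 and CNF4, 1 for CNF5 and CNF6, and 1 for CNF7, CNF8 and MCC. A control group with its exposures is called an experiment.

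Arrays were read with Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes. The authors deposited 1 table of relative values on a log scale, taken here as log2, with 1 column per group and no column per sample. It holds 41000 probes and 91 control features. How the 4 samples of a group were combined, how arrays were scaled and how probes were centred are not given in the sources used here. Each printed value is therefore the authors' group value, with no SD and no n. The highest value in the table, 7.23, excludes base 10 as a plausible log base. It does not tell base 2 from the natural logarithm, so a reading of the values as natural logs was tried as an alternative.

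Every probe was centred near 0 by the authors, so the table keeps no expression level. The centring was checked by the variance, over probes, of the mean of the columns of an experiment. It was 0.00875 for the grouping in the labels and 0.0162 in the median of 20000 random groupings of the columns, of which 1 reached the value of the labels' grouping and none was lower. The columns thus appear to have been centred within each experiment. For this reason vehicle controls of different experiments were not compared or pooled. Each exposure was compared with its own control, and exposures of different experiments by the difference of these differences.

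The design fixed before the data were examined was a limma fit over 52 arrays. It also fixed what to do with a table of 1 column per group, which was followed here: no test, differences on the log2 scale, and items named by size. A probe was counted as changed at an absolute difference of at least 1 on the log2 scale (2-fold), and a second count used 2 (4-fold). "Rose" and "fell" below mean past 2-fold in the group values and carry no statement on significance. The spread between the samples of a group is unknown, so no difference could be set against it.

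The array's probe identifiers are not paired with genes in the table, and 0 of them matched the RefSeq gene table of assembly GRCh38.p14. No gene is therefore named, and the 35 gene lists fixed beforehand could not be applied. The rule for named items was the probes that rose most and fell most in each comparison by size. Its filter on mean level could not be used on centred values, and at most 2 identifiers in each direction are given per comparison. Probes picked outside this rule are named as such.

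Similarity between exposures was described by Pearson's r over probes, which are not independent replicates, and by the overlap of changed probes, set beside the number that independent lists would give. Of the pairs of exposures, 30 have separate vehicle controls and 6 share one. Simulated unchanged groups gave r = 0.50 and a covariance of 0.0240 with a shared control, and r = 0.0032 with separate controls. The simulated noise was equal in all columns and was taken from the spread of the 91 control features. The deposited columns spread unequally over probes. With no effect, a shared control of wider spread than its exposures gives a higher r than the simulated one, and one of narrower spread a lower r. A control could not be split, since it has 1 value.

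The counting was tested on simulated data with 41000 probes for each of the 9 exposures, at a noise SD of 0.154 per column. Simulated changes of 1.5 were recovered in 98.0% of cases for CNF1 and 100.0% for MCC, and changes of 3.0 in 100.0% for both. This noise is that of the control features and leaves out the spread between cultures. Alternatives were quantile normalization of the columns, centring of each column on its median, a shift by the spike-in control features, the natural-log reading, and for the mean of the nanofibrils leaving out each in turn. Quantile normalization gives all columns 1 distribution, so it evens out higher and lower by construction. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.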

Results

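Expression was profiled in BEAS-2B bronchial epithelial cells after 48 h with 8 cellulose nanofibrils (thin fibres prepared from cellulose) or with microcrystalline cellulose (MCC), in order to compare the nanofibrils with MCC. There were 9 exposed groups and 4 vehicle control groups of 4 samples each, and 41000 probes were measured. The deposited table gives 1 value per group and no value per sample. All differences below are therefore between the authors' group values, without replicate error and without a test. The probes could not be matched to genes and are given by their identifiers.

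The exposures differed in how many probes moved and in which direction. CNF8 and MCC had mainly higher probes, with 2015 and 1621 raised at least 2-fold and 89 and 93 lowered. CNF5 and CNF6 had mainly lower probes, with 752 and 1340 lowered and 142 and 52 raised. CNF3 raised 1019 and lowered 445 probes as deposited, but 717 and 892 after a shift by the spike-in features. CNF2 raised 354 and lowered 548, CNF1 224 and 105, CNF4 64 and 331, and CNF7 96 and 168. Of the 41000 probes, 35157 stayed within 2-fold in every exposure and 3375 passed it in 1 exposure.

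**Figure D1:**
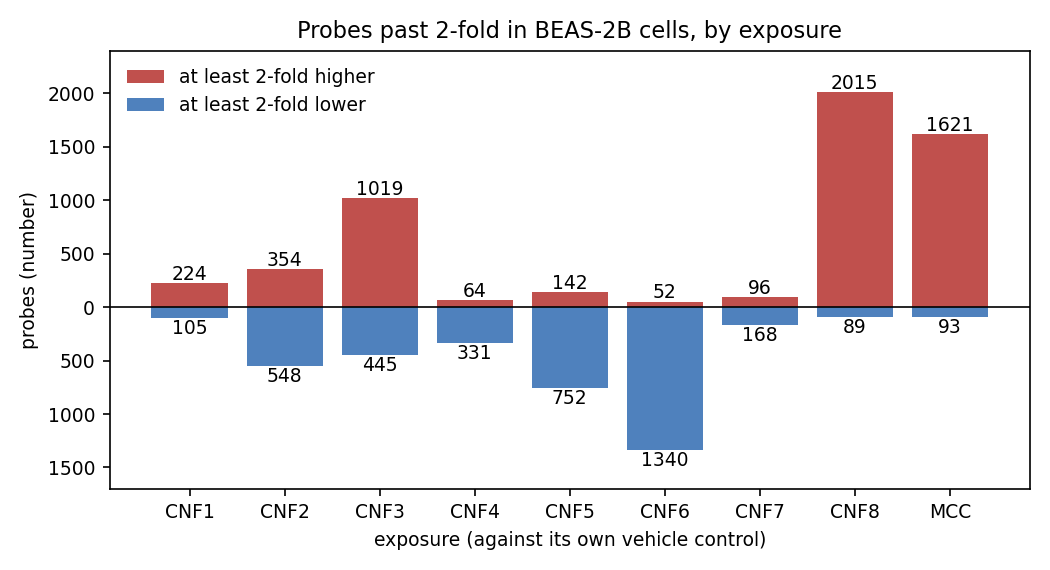
Number of probes at least 2-fold higher (upward bars) and at least 2-fold lower (downward bars) than the matched vehicle control, for 8 cellulose nanofibrils and MCC; each group has 1 value per probe, so there is no error bar. CNF8 (2015) and MCC (1621) have the tallest upward bars and CNF6 (1340) the longest downward bar.

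The columns also differed in their overall level, which bears on these counts. The median difference over all probes was 0.10 on the log2 scale in CNF1, -0.14 in CNF2, -0.01 in CNF3, -0.12 in CNF4, -0.03 in CNF5, -0.12 in CNF6, 0.04 in CNF7, 0.10 in CNF8 and 0.12 in MCC. The negative control feature, which reads background, shifted by -0.37 in CNF2, -0.39 in CNF4, 0.28 in CNF8 and 0.33 in MCC. The median of the 10 spike-in features shifted by -0.40 in CNF2, -0.39 in CNF4, -0.27 in CNF8 and -0.12 in MCC. None of the 91 control features was 2-fold higher in any of the 9 exposures, and 1 each was 2-fold lower in CNF5 and CNF6.

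**Figure D2:**
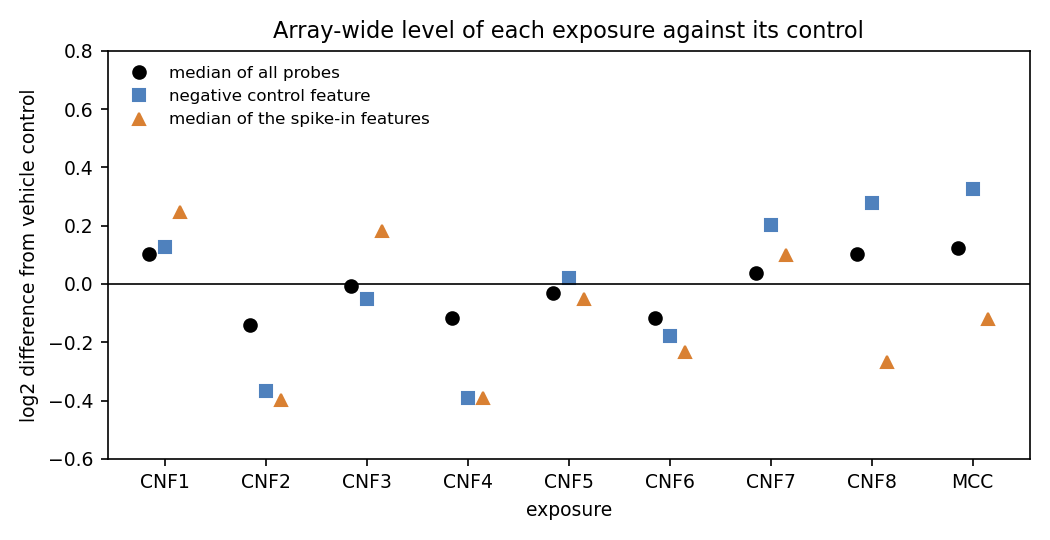
Log2 difference of each exposure from its vehicle control for the median of all 41000 probes (circles), the negative control feature (squares) and the median of the spike-in features (triangles). In CNF2 and CNF4 the 3 measures lie below 0, while in CNF8 and MCC the spike-in features lie below 0 and the negative feature above it, at 0.28 and 0.33.

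As deposited, CNF2 and CNF3 gave the largest single changes among the 9 exposures. The most raised probe in CNF3, A_23_P165624, was 7.64 above its control on the log2 scale, or 198.8-fold, and it was 6.35 above control in CNF2; quantile normalization lowered these to 3.21 and 2.79. The most raised probe in CNF2, A_23_P55632, was 6.74 above control there and 5.18 in CNF3, or 3.73 and 2.22 under quantile normalization. The same 2 probes were within 1 of their control in CNF1, CNF4, CNF5, CNF6, CNF7 and MCC, and were 1.89 and 1.00 above it in CNF8. The 1.00 of A_23_P55632 became 0.52 under quantile normalization and 0.91 after median centring. A_23_P84860 had the largest fall in CNF3, at -4.16, and stood at -2.94 in CNF2. The largest fall in CNF2 was that of A_23_P118894, at -3.10, with -1.87 in CNF3. Under quantile normalization, A_23_P84860 stood at -2.46 in CNF3 and A_23_P118894 at -2.18 in CNF2. These are smaller falls than that of A_24_P934592 in CNF1, at -2.93. At least 4-fold, 155 probes rose and 23 fell in CNF3, and 69 rose and 29 fell in CNF2. Centring the columns on their medians turned the balance in CNF2, with 59.9% of its changed probes higher against 39.2% as deposited.

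CNF2 and CNF3 belong to different experiments with separate controls, and part of their changes fell on the same probes. Of the raised probes, 174 were common to both, where independent lists would share 8.80. Of the lowered probes, 110 were common, where independent lists would share 5.95; quantile normalization gave 48, against 3.41. None rose in CNF2 and fell in CNF3, while 18 did the opposite, against 13.6 in independent lists. Over all probes the correlation was modest (r = 0.27). The 174 probes had median differences of 1.78 in CNF2 and 1.90 in CNF3. Their median was 0.50 in CNF8, where 25 of them rose, 0.21 in MCC, 0.22 in CNF1 and 0.19 in CNF4. In CNF5, CNF6 and CNF7 it was 0.03, 0.05 and 0.16.

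**Figure D3:**
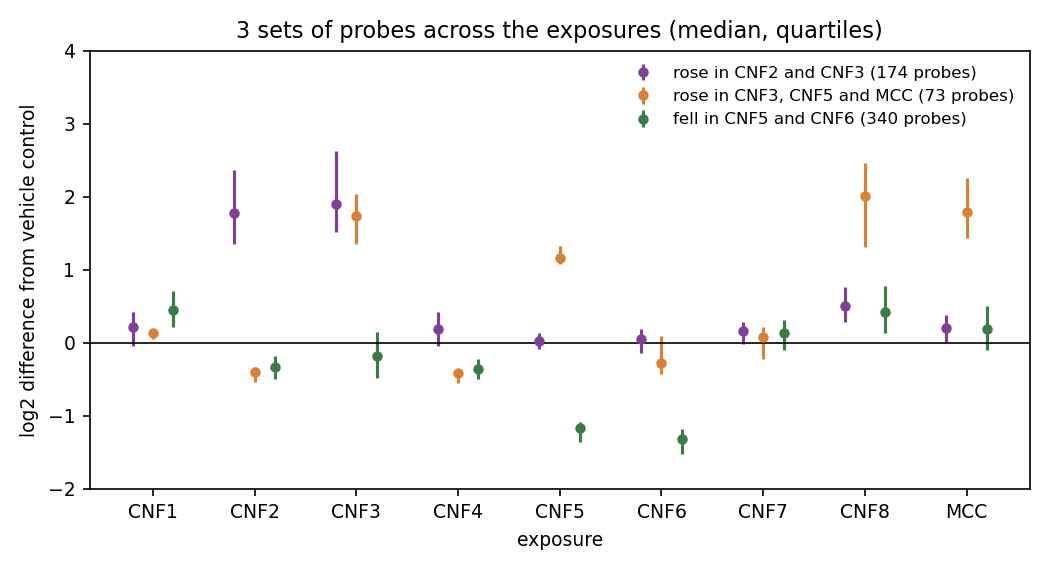
Median log2 difference from the vehicle control (points) with quartiles over probes (bars) in each exposure, for 174 probes that rose in CNF2 and CNF3, 73 that rose in CNF3, CNF5 and MCC, and 340 that fell in CNF5 and CNF6. The exposures used to choose a set pass 2-fold by construction; outside them, the 73 probes stand at 2.01 in CNF8 and near or below 0 in the other nanofibrils.

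CNF8 and MCC raised many probes in common. The probe most raised by CNF8, A_24_P926915, was 3.42 above control, and 2.96 in MCC. The probe most raised by MCC, A_24_P620066, was 3.29 above control, and 3.02 in CNF8. As deposited, the largest falls were smaller, at -1.74 for A_32_P35106 in CNF8 and -1.79 for A_32_P221774 in MCC. Quantile normalization turned this order for these probes. It took the falls to -2.80 in CNF8 and -2.84 in MCC, and the rises of A_24_P926915 in CNF8 and A_24_P620066 in MCC to 2.55 and 2.69. Which probes rose and fell most under that scaling was not computed. The 2 exposures raised 1058 probes in common, against 79.7 in independent lists, and correlated with r = 0.82 over all probes. They share a vehicle control, which alone gives r = 0.50 in simulated unchanged groups, and part of the overlap may come from it. Quantile normalization shortened the lists and gave an overlap of 384, against 10.05. It took the higher share of changed probes to 60.2% in CNF8 and 58.3% in MCC, from 95.8% and 94.6%. Since it evens out higher and lower by construction, these shares cannot tell whether the predominance of higher probes holds. In the experiment of CNF2 and CNF4, 31.3% of the 1058 probes followed the negative control feature within 0.1, against 15.7% of all probes. Over the columns of all 3 other experiments, and within 0.25, 6.45% of the probes raised in CNF8 and 6.29% of those raised in MCC did so, against 19.0% of all probes; CNF3, in which 399 of the 1058 rose, is among these columns. The covariance was 0.151 against 0.0240 in the simulation. The simulation gave all columns equal noise, whereas the SD over probes was 0.22 in this control, 0.29 in CNF8 and 0.26 in MCC. CNF7 has the same control, and in it the 1058 probes had a median of 0.18, with 13 of them raised.

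Part of this rise was also seen in CNF3 and CNF5, which have other controls. CNF3 shared 469 raised probes with CNF8 and 469 with MCC, where independent lists would share 50.1 and 40.3. Quantile normalization gave 127 against 7.82 and 151 against 8.25. In the experiment of CNF2 and CNF4, 30.9% of the probes raised in CNF3 and MCC followed the negative feature within 0.1. CNF5 shared 97 of its 142 raised probes with CNF8 and 93 with MCC, against 6.98 and 5.61. It also lowered 84 probes that CNF8 raised and 73 that MCC raised, against 37.0 and 29.7. Over all probes, CNF5 had r = -0.03 with CNF8 and 0.02 with MCC. CNF3 and CNF5 shared 84, against 3.53. Altogether 73 probes rose in CNF3, CNF5 and MCC, where independent lists would share 0.140, and 65 of the 73 rose in CNF8 too. In the exposures that share the controls of these groups, the median of the 73 probes was 0.13 in CNF1, -0.27 in CNF6 and 0.08 in CNF7. In CNF2 and CNF4 it was -0.40 and -0.41, close to the shift of the negative feature there. A_24_P926915 was raised by 3.35 in CNF3 and 1.03 in CNF5, but stood at -0.86 in CNF7.

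CNF5 and CNF6 lowered probes in common. The largest fall in CNF5 was that of A_23_P377094, at -2.52, and it stood at -1.40 in CNF6. The largest fall in CNF6 was that of A_23_P108314, at -2.70, and it stood at -1.66 in CNF5. Both exposures lowered 340 probes, against 24.6 in independent lists. They share a vehicle control. Their correlation of 0.55 was close to the 0.50 that the simulation gave for a shared control with no effect. The covariance was 0.0680 against 0.0240 in the simulation, which gave all columns equal noise. The SD over probes was 0.26 in this control, 0.19 in CNF5 and 0.21 in CNF6. A control of wide spread gives a larger covariance with no common effect, so the excess over the simulation cannot show one. Control features moved the same way, with 12 of 91 lower by at least 0.5 in CNF5 and 19 in CNF6. The most raised probe was A_23_P73198 in CNF5, at 1.89, and A_24_P929762 in CNF6, at 2.09. Under quantile normalization, 51.8% of the changed probes were higher in CNF5 and 47.0% in CNF6, against 15.9% and 3.7% as deposited. That scaling evens out higher and lower by construction, so it cannot tell whether the predominance of lower probes holds.

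CNF1, CNF4 and CNF7 changed the fewest probes in the values as deposited. In CNF1, A_23_P85218 rose by 2.54 and A_24_P934592 stood at -2.09. In CNF4, A_23_P163402 rose by 3.17 and A_23_P436618 stood at -2.09. In CNF7, A_24_P922401 rose by 2.13 and A_32_P171253 stood at -1.99. Past 4-fold, CNF1 had 2 raised probes and 1 lowered, CNF4 had 1 of each, and CNF7 had 3 raised and 0 lowered. CNF4 and CNF2 share a control, and lowered 164 probes in common and raised 28, against 4.42 and 0.553 in independent lists. The correlation was 0.68, against 0.50 in the simulation of a shared control with equal noise in all columns. The SD over probes was 0.25 in this control, 0.24 in CNF2 and 0.13 in CNF4. With such unequal spread, 0.50 is not the value to set beside this pair. The negative feature lay lower in both, by -0.37 in CNF2 and -0.39 in CNF4. After the shift by the spike-in features the common falls numbered 10, against 0.120, and the common rises 472, against 26.7. The share of higher probes depended on the scaling. In CNF4 it was 16.2% as deposited and 37.7% after median centring and 95.1% after the shift by the spike-in features. In CNF1 it was 68.1% as deposited and 14.6% after that shift.

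Set against MCC, the question of the series, CNF8 differed least among the 8 nanofibrils, with 255 probes at least 2-fold higher and 68 lower. CNF7, the other nanofibril measured beside MCC, had 42 higher and 1547 lower, or 364 and 550 under quantile normalization. Against the shared vehicle, CNF7 lowered 168 probes and MCC raised 1621. A probe counted as lower than in MCC need not have fallen with the nanofibril. The direct difference was largest upward for A_23_P165624 in CNF8, at 2.42, and downward for A_24_P926915 in CNF7, at -3.82. The other 6 nanofibrils can be compared with MCC only across experiments. CNF1 had 324 probes higher and 1496 lower, CNF2 894 and 4256, CNF3 361 and 1368, CNF4 313 and 4082, CNF5 127 and 3507, and CNF6 346 and 5441. These counts carry the variation of 4 group values each, and their totals over both directions were larger than those against the vehicle. The rise in MCC bears on them too, since CNF1 lowered 105 probes against vehicle. Against vehicle the negative feature, which reads background, stood at -0.37 in CNF2 and -0.39 in CNF4 but at 0.33 in MCC. It stood at -0.18 in CNF6, -0.05 in CNF3, 0.02 in CNF5, 0.13 in CNF1, 0.20 in CNF7 and 0.28 in CNF8. Background alone thus lay lower in each of the 8 nanofibrils than in MCC, most so in CNF2 and CNF4. Part of their lower counts may come from dim probes. A_23_P165624 was 6.88 higher with CNF2 and 8.16 higher with CNF3 than with MCC, or 3.76 and 4.18 under quantile normalization. A_24_P926813 stood at -4.06 in CNF2 and -4.16 in CNF4 against MCC. Lower probes outnumbered higher ones in each of these 6 comparisons as deposited. Quantile normalization, which evens out higher and lower by construction, gave 1890 higher and 1879 lower in CNF2 and 1883 and 1809 in CNF6. It gave 592 and 903 in CNF1, 442 and 573 in CNF3, 1476 and 2042 in CNF4 and 673 and 1198 in CNF5, and the shift by the spike-in features gave 62 and 3005 in CNF1 and 200 and 3152 in CNF3.

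Nanofibrils of the same experiment could be compared directly. CNF1 was at least 2-fold above CNF3 in 711 probes and below it in 784, a balance that turned to 2072 and 1535 with the values read as natural logs. The widest gap was that of A_23_P165624, at -7.34, or -2.93 under quantile normalization. CNF2 was above CNF4 in 278 and below it in 219, with A_23_P165624 at 6.31 and A_23_P163402 at -5.78. Quantile normalization took these 2 values to 2.88 and -4.50. CNF5 was above CNF6 in 656 probes and below it in 243, with A_24_P934592 at 2.38, but the shift by the spike-in features turned the balance to 357 above and 462 below. CNF7 was above CNF8 in 57 and below it in 1868, with A_24_P926915 at -4.28. Quantile normalization, which evens out higher and lower by construction, brought this to 422 above and 541 below.

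Few probes moved alike in the 8 nanofibrils. The mean of the 8 differences passed 2-fold upward for 23 probes and downward for 3, and 12 and 2 of these had the same sign in each nanofibril. The mean was highest for A_23_P165624, at 2.06, and lowest for A_23_P84860, at -1.35. Without CNF3 the count of 26 probes dropped to 7, and without CNF2 to 12. In at least 2 nanofibrils, 760 probes rose and 764 fell; in at least 4, 7 rose and 8 fell. A total of 388 probes lay above their control in all 8 nanofibrils and 571 below. The number expected with no effect was not computed, and nanofibrils that share a control tend to lie on the same side of it. These 2 counts are therefore no sign of a common response.

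The correlation of differences over probes ranged from -0.47 to 0.49 in the 30 pairs of exposures with separate controls, and 13 of these were above 0. The highest was that of CNF3 with CNF8, and the lowest that of CNF1 with CNF6. Of the pairs with a shared control, CNF1 with CNF3 had r = 0.37, CNF7 with CNF8 0.45 and CNF7 with MCC 0.53. The simulated 0.50 holds for equal noise in all columns and is not the value to set beside them. The SD over probes was 0.19 in the control of CNF1 and CNF3, 0.20 in CNF1 and 0.32 in CNF3. It was 0.22 in the control of the other pairs, 0.18 in CNF7, 0.29 in CNF8 and 0.26 in MCC.

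**Figure D4:**
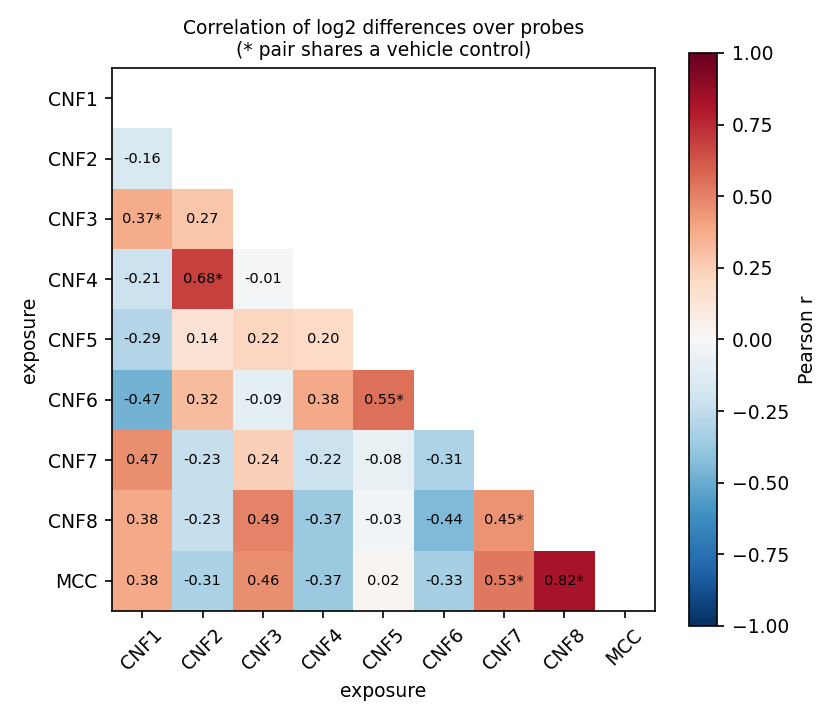
Pearson correlation over 41000 probes of the log2 differences from vehicle, for each pair of exposures (colour scale from -1 to 1); an asterisk marks pairs that share a vehicle control. CNF8 with MCC has the highest value (0.82, shared control), and CNF3 with CNF8 the highest among pairs with separate controls (0.49).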

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

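Some probes moved past 2-fold in opposite directions in a pair of nanofibrils that share a vehicle control. With 1 value per group, these differences were not tested, and the probes were picked after their values were seen. CNF2 and CNF4 had 4 such probes. A_23_P163402, the most raised probe of CNF4 at 3.17, stood at -2.62 in CNF2, and at -1.57 in CNF3 of another experiment. A_23_P207213 stood at 1.31 in CNF4, -2.26 in CNF2 and -1.18 in CNF3. CNF7 and CNF8 had 3 such probes, among them A_32_P101002 at -1.45 in CNF7 and 1.26 in CNF8. CNF1 and CNF3 had 2, A_32_P118013 at -1.18 and 1.90 and A_32_P206308 at -1.19 and 1.09. Independent lists would give CNF2 and CNF4 3.71 opposite probes, CNF7 and CNF8 8.46, and CNF1 and CNF3 5.04. The 4 observed in CNF2 and CNF4 were thus about that number and those of the other 2 pairs below it, and a shared control lowers such counts. The gap of A_23_P163402 was past 2-fold on both sides under each scaling tried, whereas quantile normalization left A_32_P101002 at 0.70 in CNF8, A_32_P118013 at 0.91 in CNF3 and A_32_P206308 at 0.65 in CNF3.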

How the results depend on the processing

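The shift by the spike-in features, the natural-log reading and leaving out single nanofibrils were chosen after seeing the data; quantile normalization and median centring were planned. No paired analysis was possible because the table has 1 column per group and no replicate values. For the same reason, leaving out replicates, other variance models, other arrays in the fit, thresholds on p and split controls were not run. Filters and floors on dim signal, background correction and the slide as a block were not run because levels and scanner values are not in the table. Gene lists and probes per gene were not run for want of gene names, nor pooled controls because of the centring. What weak signal limits is therefore unknown. Of 62 single-probe values, none changed sign under the 3 other scalings. This was close to fixed beforehand, since most were picked by size and 2 of the scalings move each comparison by a small constant. Of the 61 past 2-fold, 8 came under it in at least 1 scaling (6 under quantile normalization, 2 under median centring, 3 under the spike-in shift). Each overlap followed exceeded that of independent lists under the 3 other scalings, by 2.68 times or more. For the pairs that share a control (CNF8 with MCC, CNF5 with CNF6, CNF2 with CNF4), independent lists are not the number expected with no effect. Quantile normalization took A_23_P165624 in CNF3 from 7.64 to 3.21. Median centring left the 22 counts within 1.5 times, and also the common rises and falls, except those of CNF2 and CNF4, whose common rises became 69 and common falls 86; the cause was not tested. The share of higher probes then moved from 68.1% to 56.0% in CNF1, 39.2% to 59.9% in CNF2 and 16.2% to 37.7% in CNF4. Against MCC it moved from 17.4% to 41.2% in CNF2, 20.9% to 32.8% in CNF3, 7.1% to 25.5% in CNF4 and 6.0% to 17.8% in CNF6.

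Quantile normalization gives columns of different spread 1 distribution, which by construction evens out higher and lower. It gave 692 changed probes in CNF1 (44.2% higher), 937 in CNF3 (54.7%, from 69.6%), 782 in CNF4 (50.5%), 700 in CNF6 (47.0%, from 3.7%) and 493 in CNF7. It gave 1038 in CNF8 (60.2%, from 95.8%) and 1130 in MCC (58.3%, from 94.6%). The share became 58.7% in CNF2 and 51.8% in CNF5, from 15.9%. Against MCC it gave 1015 in CNF3 (43.5%), 1871 in CNF5 (36.0%, from 3.5%), 3692 in CNF6 (51.0%), 914 in CNF7 (39.8%, from 2.6%) and 143 in CNF8 (60.8%, from 78.9%). The share became 39.6% in CNF1, from 17.8%, 50.1% in CNF2 and 42.0% in CNF4. CNF1 against CNF3 had 843, CNF2 against CNF4 795, CNF7 against CNF8 963 (43.8%, from 3.0%) and the mean of the 8 nanofibrils 15. CNF5 against CNF6 had 52.2% higher, from 73.0%. Common falls numbered 48 in CNF2 and CNF3 and 120 in CNF5 and CNF6. Common rises numbered 102 in CNF2 and CNF4, 127 in CNF3 and CNF8, 151 in CNF3 and MCC and 384 in CNF8 and MCC.

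The shift by the spike-in features moves each exposure by 1 constant. It gave 1762 in CNF2 (92.0% higher), 711 in CNF4 (95.1%), 721 in CNF6 (180 higher and 541 lower) and 3591 in CNF8. The share became 14.6% in CNF1, 44.6% in CNF3 and 22.0% in CNF7, from 36.4%. Against MCC it gave 3067 in CNF1 (2.0%), 3352 in CNF3 (6.0%), 2409 in CNF7 and 507 in CNF8 (93.9%), with 48.6% higher in CNF2 and 33.7% in CNF4. CNF7 against CNF8 had 3999, CNF5 against CNF6 43.6% higher, and common falls in CNF5 and CNF6 numbered 196. CNF2 and CNF4 had 472 common rises and 10 common falls.

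Read as natural logs, 2-fold is a difference of 0.693, which by construction raises the counts. They became 1641 in CNF1, 2998 in CNF2, 3458 in CNF3 (57.1% higher), 1787 in CNF4, 2868 in CNF5, 4335 in CNF6, 890 in CNF7 (23.3%), 4259 in CNF8 and 3536 in MCC. Against MCC they became 3673, 11266, 4060, 9592, 7369, 11052, 3049 and 1348 in CNF1 to CNF8. In the comparison with MCC, the negative feature itself passed this limit in CNF4 and came close to it in CNF2. CNF1 against CNF3 had 3607 (57.4%, from 47.6%), CNF2 against CNF4 1264, CNF5 against CNF6 2289, CNF7 against CNF8 3704, and the mean of the nanofibrils 115 (69.6%, from 88.5%). Common rises became 321 in CNF2 and CNF3, 260 in CNF2 and CNF4, 282 in CNF5 and CNF8, 1020 in CNF3 and CNF8, 994 in CNF3 and MCC, 262 in CNF3 and CNF5, 281 in CNF5 and MCC, 2079 in CNF8 and MCC and 221 in CNF3, CNF5 and MCC. Common falls became 357 in CNF2 and CNF3, 778 in CNF2 and CNF4 and 1520 in CNF5 and CNF6. The mean of the nanofibrils, 26 probes, became 12 without CNF2, 7 without CNF3, 42 without CNF4, 40 without CNF5 and 41 without CNF6; beyond the fewer groups averaged, the cause was not tested.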

Other observations

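The tests in this part were chosen after the patterns were seen. Pairs of exposures with separate controls also changed some probes in opposite directions. Of the probes lowered by CNF6, 325 were raised by CNF8, against 65.9 in independent lists, and 174 by MCC, against 52.98. Under quantile normalization, which shortened the lists, these were 35 against 5.66 and 16 against 5.96. Of the probes raised by CNF1, 52 were lowered by CNF6 and 44 by CNF5, against 7.32 and 4.11. The shift by the spike-in features shortened the CNF1 list too, and gave 14 against 0.845 and 11 against 0.955. The 340 probes that fell in CNF5 and CNF6 had a median of 0.44 in CNF1, 0.42 in CNF8, 0.19 in MCC and 0.13 in CNF7. In CNF2, CNF4 and CNF3 their median lay below 0, at -0.33, -0.36 and -0.18. A_32_P528967, picked because it passed 2-fold in 7 exposures, was at 1.28 in CNF1, 1.52 in CNF8 and 1.04 in MCC, and at -1.11 in CNF2, -1.35 in CNF4, -1.38 in CNF5 and -1.57 in CNF6. It came under 2-fold in MCC under quantile normalization (0.80) and median centring (0.93), and in CNF2 (-0.72) and CNF4 (-0.96) after the spike-in shift. The median of the 91 control features had the same signs, though smaller values. It was 0.18 in CNF1, 0.28 in CNF8 and 0.30 in MCC, and -0.37 in CNF2, -0.39 in CNF4, -0.07 in CNF5 and -0.25 in CNF6. Opposite signs were thus not confined to probes, and the overlaps above cannot be assigned to the exposures.

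The first pattern weighed is the set of 174 probes raised by CNF2 and CNF3. Chance values of the controls are a poor candidate cause, since with CNF4 and CNF1 of the same experiments in place of the controls 158 probes rose in both, against 5.32 in independent lists. Scaling differences of the kind that quantile normalization removes are argued against as well, since it left 136 probes, against 5.87. Median centring and the spike-in shift gave 199 and 212. They move each exposure by a small constant and could hardly have removed the set, so no conclusion is drawn from them. A scaling difference that depends on signal level could not be tested on these probes, whose level the table does not keep. The 110 probes lowered by both became 48 under quantile normalization, against 3.41. A property that CNF2 and CNF3 share stays open as a hypothesis and was not tested.

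The second pattern is the set of 73 probes raised by CNF3, CNF5 and MCC. Low control values are argued against, since the same probes had a median of at most 0.13 in CNF1, CNF6 and CNF7, which share those controls. Scaling differences of the kind that quantile normalization removes are argued against too, since it left 62 probes, against 0.0670 in independent lists. Median centring and the spike-in shift gave 76 and 70. They move each exposure by a small constant and could hardly have removed this set either, so no conclusion is drawn from them. A scaling difference that depends on signal level could not be tested on these probes, whose level the table does not keep. The control features show that it is a live candidate in part of the exposures. The negative feature stood at 0.28 in CNF8 and 0.33 in MCC, where the spike-in median was -0.27 and -0.12. In CNF3 the order was the reverse, at -0.05 and 0.18, and in CNF5 the values were 0.02 and -0.05. Independent lists also take no account of dim signal that probes share. Many of the 73 may be probes near background. In the experiment of CNF2 and CNF4, which had no part in choosing them, 47.9% followed the negative control feature within 0.1 in all 3 columns, against 15.7% of all probes. A rise in dim signal on some arrays and an effect of these materials both stay open; the second was not tested.

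The third pattern is the set of 340 probes lowered by CNF5 and CNF6. The lowest count over the other scalings was 120, but since the exposures share a control, independent lists (2.81) do not give the number expected with no effect, and scaling stays open for part of the set. High values in the shared control are a candidate explanation that the control features go with, since 9.89% of them (9 of 91) were at least 0.5 below that control in both exposures. CNF2 and CNF4 had 8 such features, but there the negative feature itself had shifted by -0.37 and -0.39, against 0.02 in CNF5 and -0.18 in CNF6. The 9 features also lay above control in CNF1 and CNF8 and below it in CNF2 and CNF4, as the 340 probes did in the median. In CNF3, CNF7 and MCC their signs were mixed. The median of all 91 control features was 0.18 in CNF1, 0.28 in CNF8, 0.30 in MCC and 0.18 in CNF7. It was -0.37 in CNF2, -0.39 in CNF4 and -0.02 in CNF3, each with the sign of the 340 probes. An effect common to CNF5 and CNF6 was not tested and cannot be told apart here from a cause that also moves control features.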
